A study of Mus musculus with 5 samples.

How the data were processed

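Messenger RNA of sorted LSK bone marrow cells from C57BL/6 mice was sequenced after a stranded library preparation, per the labels' protocols. The deposited table held raw read counts for 33862 RefSeq transcripts in 5 libraries, 3 titled KO and 2 titled WT. Per the submitters' processing notes, STAR, Subread 1.4.5-p1 and featureCounts and the genome build mm9 (NCBIM37) were used; settings, strand use and the treatment of reads shared between transcripts are not given in the sources used here. Groups came from the titles. Antisense or overlapping genes and near-identical copies cannot be told apart without these settings.

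Transcripts of a gene carried the same reads: of 3860 genes with more than 1 transcript of at least 100 counts, the lowest transcript had at least 90% of the highest in 2914, with a median of 98.7%. The transcript with the most counts over all libraries was therefore kept for each gene. Names came from the RefSeq table of GRCm38 for 33485 transcripts and from the GENCODE table for 188, and 189 matched neither; those without a symbol held 0.362% to 0.459% of counts. This left 24399 genes. Of 13404 genes with at least 100 counts, 62 had counts identical to those of another gene, such as the haemoglobin genes Hba-a1 and Hba-a2, and are uncertain for that reason. Total counts over all transcripts were 57535625, 63444643 and 63736139 in KO libraries 1 to 3 and 48113632 and 62238842 in WT libraries 1 and 2. With 1 transcript per gene they were 36060320, 39423495, 39691066, 29964556 and 38674416, so that 3 counts, taken as the floor, equalled 0.076 to 0.1 CPM.

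Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3) by the robust quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 18.9%. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. Of 29 lists fixed before the data were examined, 27 were tested; the mitochondrial-encoded list had 0 measured genes and the sex-linked list had 2 tested, under the minimum of 5. Another 8 lists were chosen after the results were seen. The named genes were 10 genes fixed beforehand, the 8 higher and 8 lower with the largest change among named genes past the threshold that separated the groups at a mean of at least 1 CPM, and for each list up to 4 members past the threshold with the smallest p or, where fewer than 2 passed, the 2 most abundant. Others named were chosen after their values were seen: further called members of lists and genes of the lists added later. Some genes, and results and 1 list that need them, are not reported here.

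In simulated counts for the same design over 14213 genes, the test recovered 43.8% of genes changed 1.5-fold, 63.5% changed 2-fold and 85.7% changed 4-fold, and 6.9% of its calls fell on unchanged genes. Of 200 random lists, 4.5% had a camera p under 0.05. The simulated genes varied independently, so this share does not carry over to lists whose genes vary together. No library-wide effect was simulated, such as the length trend of KO library 1. The recovery and the share of calls on unchanged genes may therefore differ in the real libraries. Among the lists fixed beforehand the estimated correlation reached 0.826, in the list of stem cell ageing. Alternatives were other scalings, DESeq2 1.42.0, limma with sample weights, other filters and thresholds, a replicate block and each library left out. Summed transcripts, every transcript tested, protocadherin gamma genes counted once, and offsets for transcript length and GC content were added after the data were seen. Bootstrap bounds used 10000 resamples over genes, and Python 3.11.15 with scipy 1.17.1 was used for exact tests. The bootstrap bounds cover the spread over the genes of a list only, not counting error or the spread between libraries.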

Results

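Messenger RNA was profiled in LSK cells, the lineage-negative, Sca1-positive and cKit-positive fraction of mouse bone marrow that holds haematopoietic stem cells and multipotent progenitors. The cells were sorted from C57BL/6 mice aged 12 months. The comparison asks how the transcriptome of these cells differs between knockout and wild-type mice. There were 3 libraries titled KO and 2 titled WT. The genotype field of the KO-titled libraries gives a heterozygous genotype, so they are called KO-labelled here. Total counts, with 1 transcript kept per gene, ran from 29964556 in WT library 1 to 39691066 in KO library 3. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical. Levels are given as CPM, counts scaled to the library total adjusted by the TMM composition factor, as mean ± SD, with n = 3 for KO-labelled and n = 2 for WT. Fold changes are KO-labelled against WT and carry the standard error (SE) and adjusted p of edgeR's quasi-likelihood test.

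All 5 libraries expressed Xist, the transcript of the inactive X chromosome, at 11561 to 22663 counts, and no Y-linked gene of the list (Ddx3y, Eif2s3y, Kdm5d, Uty) exceeded 4 counts in any library.

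Across the transcriptome, 287 of 14565 tested genes changed, 115 higher and 172 lower in the KO-labelled libraries. The genes that rose most were Chst1, a carbohydrate sulfotransferase (4.12 ± 0.58 on the log2 scale), Slamf9 (3.62 ± 0.80), Hepacam2 (2.54 ± 0.46) and the red cell anion exchanger Slc4a1 (2.21 ± 0.52). Ifi205, an interferon-inducible gene (2.08 ± 0.31), Aldh1a7 (2.0 ± 0.43), BC048507 (1.94 ± 0.35) and the lymphoid surface protein Ly6d (1.93 ± 0.29) followed. Among the genes that fell most were the lectin-like receptor Klrb1a (-5.33 ± 0.95), Pianp (-3.39 ± 0.24), the calcium sensor Rcvrn (-2.69 ± 0.59) and the mucin Muc1 (-2.58 ± 0.27). The tight junction gene Cldn5 (-2.49 ± 0.31), Tmem215 (-2.42 ± 0.31) and the complement gene C4b (-2.17 ± 0.49) also fell. Chst1 stood at 7.75 ± 2.90 CPM in KO-labelled and 0.425 ± 0.412 CPM in WT libraries, and Pianp at 2.32 ± 0.407 against 24.3 ± 4.98 CPM. Klrb1a stood at 0.138 ± 0.217 against 5.50 ± 1.55 CPM. Its values in KO libraries 2 and 3, 0.026 and 0 CPM, lay under the floor, so the size of its fall is uncertain. Most changes were smaller: 33 of the higher and 44 of the lower genes changed at least 2-fold. All 287 genes separated the groups completely, as did 32.8% of all tested genes, against 20% by chance for 3 against 2 libraries. Of the lower genes, 25 were protocadherin gamma symbols that share exons and reads; with that locus counted once, 247 genes changed, 106 higher and 141 lower.

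The count rested on both WT libraries and moved with the KO-labelled ones. It was 6 without WT library 1, 18 without WT library 2, 675 without KO library 1 and 135 without KO library 3. Of the named genes, Pianp, Socs3 and Hsph1 passed in all 17 alternative settings, while Slc4a1 (adjusted p = 0.0499) passed in 6 of 17. The other called genes named here by the naming rule lost their call without WT library 1, and Klf1, Il1rl1, Pdgfrb, Polb, Trp53inp1 and Ndufa4 were among those that lost it without KO library 3. Across genes on log2 CPM, KO library 1 correlated with the other libraries at 0.9525 to 0.965. WT library 1 did so at 0.9525 to 0.9694, the lowest value being that with KO library 1. The libraries did not group by label throughout. KO libraries 2 and 3 had the highest value, 0.9802, but WT library 2 correlated more with them (0.9733 and 0.9708) than with WT library 1 (0.9694).

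**Figure D1:**
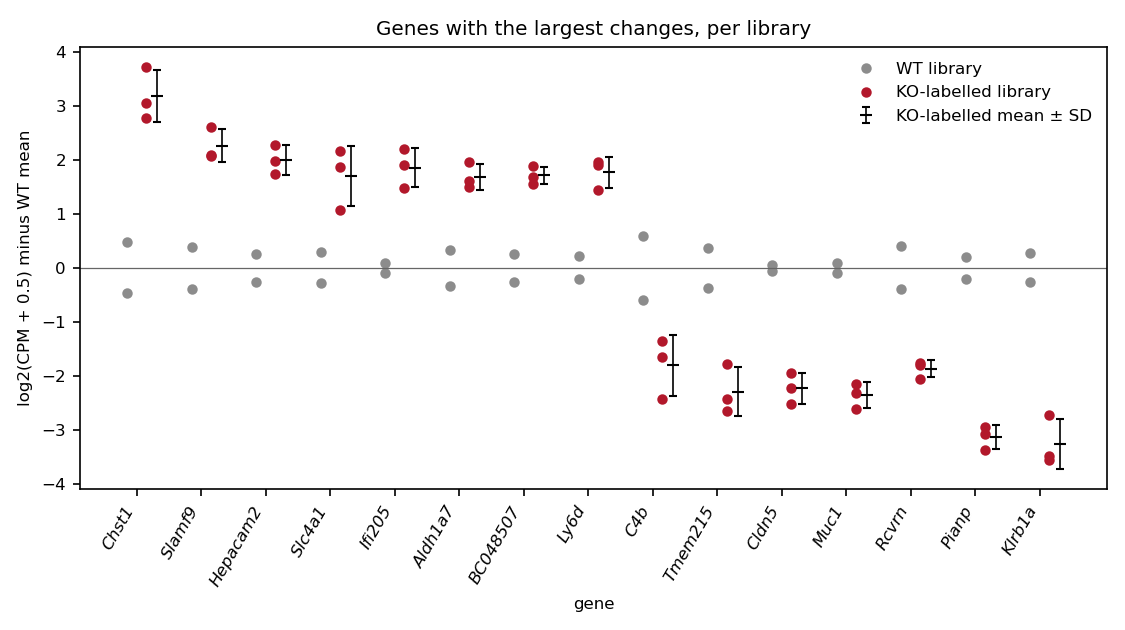
Level of the 8 genes that rose most and of 7 among those that fell most, as log2(CPM + 0.5) minus the WT mean; grey points are the 2 WT libraries, red points the 3 KO-labelled libraries, and bars the KO-labelled mean ± SD. Every KO-labelled library lies above both WT libraries for the higher genes and below both for the lower genes; the pseudocount of 0.5 makes the change of low genes such as Klrb1a smaller than the fitted value.

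A part of the erythroid genes rose in the KO-labelled libraries. Of 35 tested genes of the erythroid list, 9 rose and 0 fell over all genes, and 20 rose and 0 fell adjusted over the list alone. The 20 include Hba-a1 and Hba-a2, whose counts were identical in every library, so they are not separate measurements. Klf1, a master transcription factor of red cell development, rose 2.83-fold, from 5.06 ± 2.25 to 14.4 ± 2.17 CPM (adjusted p = 0.0169). The red cell membrane protein Ermap rose 2.28-fold (57.0 ± 7.82 against 24.9 ± 6.66 CPM), the carbonic anhydrase Car1 2.12-fold (170 ± 42.2 against 80.4 ± 0.750 CPM) and the repressor Gfi1b 1.71-fold (94.5 ± 9.73 against 55.4 ± 8.40 CPM). Gata1, the erythroid and megakaryocytic transcription factor, had a log2 fold change of 0.59 ± 0.19 that did not pass over all genes (adjusted p = 0.154), and the erythropoietin receptor Epor one of -0.15 ± 0.23 (adjusted p = 0.842). The median log2 fold change of the list was 0.59, and camera, which compares a list with all other genes, gave an adjusted p = 4.59e-10; the call was lost at adjusted p = 0.416 with an estimated correlation. Of the erythroid genes, 13 rose without KO library 1, 4 without KO library 3, 0 without WT library 1 and 1 without WT library 2. The haem and iron list held 0 calls among 26 genes over all genes or adjusted over the list alone (camera adjusted p = 0.0834; 2 higher and 1 lower without KO library 1), and of these genes Fth1 had a log2 fold change of 0.22 ± 0.09 (adjusted p = 0.294).

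Several granulocyte and monocyte genes fell. Of 33 genes of the granulocyte-monocyte progenitor list, 5 fell and 1 rose over all genes, and 10 fell and 1 rose adjusted over the list alone. Csf2rb, the shared beta chain of cytokine receptors, fell 2.10-fold (49.4 ± 5.98 against 104 ± 2.89 CPM). It may share reads with Csf2rb2, as the treatment of shared reads is not given, and is uncertain for that reason. The granule proteases Prtn3 (1.84-fold) and Ctsg (1.59-fold) and haptoglobin, Hp (1.90-fold), fell as well. Csf3r also fell, and Ly6c2, a monocyte surface marker, was the gene that rose (log2 fold change 0.54 ± 0.12). Cebpa, which drives myeloid commitment, stood at 56.7 ± 3.15 against 56.2 ± 2.97 CPM (log2 fold change 0.01 ± 0.11, adjusted p = 0.981). The list passed camera (median -0.33, adjusted p = 0.00196; adjusted p = 0.45 with an estimated correlation). Among 23 genes of the mature neutrophil and monocyte list, 3 fell and 0 rose over all genes, and 11 fell and 0 rose adjusted over the list alone. These included the calprotectin subunits S100a8 (1.77-fold lower) and S100a9 (1.69-fold lower) and the clotting factor F13a1 (1.45-fold lower). This list passed camera with a median of -0.72 (adjusted p = 9.6e-07; adjusted p = 0.416 with an estimated correlation). Without either WT library, 0 genes of both lists passed; without KO library 1, 8 progenitor and 7 mature genes fell.

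Few stem cell genes changed, although few of all tested genes did (287 of 14565). Of 30 genes of the stem cell and multipotent progenitor list, 2 fell and 0 rose, over all genes and adjusted over the list alone, among them the interferon-induced membrane protein Ifitm1 (2.13-fold, 146 ± 17.97 against 311 ± 16.8 CPM). The median was -0.04 and the list did not pass camera (adjusted p = 0.482), except with limma and sample weights (adjusted p = 0.0438). Of its genes, 4 fell without KO library 1, 0 without WT library 1 and 1 without WT library 2. In the Hox and Meis list, 1 gene of 19 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.288), and Meis1 stood at 278 ± 5.68 against 281 ± 9.22 CPM. Of 25 tested genes known to rise with age in stem cells, 3 fell over all genes, namely Selp (2.02-fold), Alcam (1.55-fold) and Ghr (1.77-fold), and 4 fell and 1 rose adjusted over the list alone. That list had a median of -0.43 (camera adjusted p = 5.37e-04; adjusted p = 0.631 with an estimated correlation), and its call was lost without KO library 2 (adjusted p = 0.0646). Of its genes, 9 fell without KO library 1, 1 without KO library 3 and 0 without either WT library, and 1 rose without KO library 2. Of 23 megakaryocyte genes, the platelet integrin Itga2b (1.57-fold), P-selectin, Selp, and Gp1ba (1.74-fold) fell, which made 3 lower and 0 higher over all genes and adjusted over the list alone. The megakaryocyte median was 0.003 while the mean was -0.07, and camera gave an adjusted p = 0.314. Without KO library 2, 1 megakaryocyte gene rose and 2 fell, and without either WT library 0 passed.

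Lymphoid and antigen presentation genes rose in part. Of 24 lymphoid priming genes, Ltb (1.68-fold), Lsp1 (1.32-fold) and the chemokine receptor Ccr9 (2.58-fold) rose over all genes, and 6 rose and 1 fell adjusted over the list alone; the list did not pass camera (adjusted p = 0.159) but did without KO library 1 (adjusted p = 0.0147), with DESeq2 (adjusted p = 0.0344), with limma and sample weights (adjusted p = 0.0322) and with the replicate number as a block (adjusted p = 0.0428). Without KO library 2, 1 lymphoid gene rose and 2 fell (median -0.07), and without KO library 3 or either WT library 0 rose and 0 fell. Of 21 tested B cell genes, 4 rose and 0 fell over all genes, and 5 rose and 0 fell adjusted over the list alone. Of those 4, the invariant chain Cd74 (2.50-fold, 501 ± 79.5 against 201 ± 23.8 CPM), H2-Aa (2.03-fold) and H2-Ab1 (1.86-fold) encode the MHC class II machinery that several cell types share, and Fcrla (3.77-fold) is a B cell gene. The B cell list passed camera (median 0.56, adjusted p = 4.82e-04; adjusted p = 0.416 with an estimated correlation), and the call was lost without WT library 2 (adjusted p = 0.11); 0 B cell genes rose without WT library 1 and 1 without WT library 2. Among 21 macrophage and dendritic cell genes, 0 passed over all genes; adjusted over the list alone 2 rose, Xcr1 and Siglech, which mark dendritic cell types and were named after their values were seen (camera adjusted p = 0.196; 1 gene rose over all genes without KO library 1 or 2). Of 25 T and NK cell genes, Klrb1c, which neighbours Klrb1a in gene order, fell 2.03-fold and no other passed, over all genes or adjusted over the list alone (median 0.05, camera adjusted p = 0.916 in the lower direction). Of 13 mast cell, basophil and eosinophil genes, Il1rl1, the interleukin-33 receptor, rose 2.07-fold, the 1 call over all genes and adjusted over the list alone. That list had a median of 0.72 (camera adjusted p = 0.0217; adjusted p = 0.556 with an estimated correlation), lost without KO library 3 (adjusted p = 0.0671), without WT library 2 (adjusted p = 0.197), with no count filter (adjusted p = 0.0795) and with an offset for transcript length (adjusted p = 0.0525). Among 14 stromal and endothelial genes, Pdgfrb fell 1.72-fold, the 1 call over all genes, and 2 fell adjusted over the list alone (camera adjusted p = 0.318).

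Some interferon response and heat shock genes rose, and 1 gene of the G2 and M phase list did. Of 38 interferon response genes, 6 rose and 0 fell over all genes, and 12 rose and 0 fell adjusted over the list alone. These included the GTPases Igtp (1.46-fold, 96.9 ± 9.49 against 66.5 ± 1.4 CPM) and Ifi47 (1.36-fold), and Rtp4 (1.53-fold). Ifitm1, named above as interferon-induced, is not on this list and fell 2.13-fold. The interferon median was 0.31 (camera adjusted p = 1.05e-07; adjusted p = 0.416 with an estimated correlation), and 16 genes rose without KO library 1, 3 without KO library 2, 1 without KO library 3 and 0 without either WT library. Of 27 immediate early and stress genes, 3 rose and 0 fell over all genes, all of them heat shock genes, and 7 rose and 0 fell adjusted over the list alone. They were the chaperones Hsph1 (2.40-fold, 305 ± 23.3 against 127 ± 4.08 CPM), Hspa8 (1.77-fold) and Dnajb1 (1.39-fold), and the list median was 0.68 (camera adjusted p = 3.34e-09; adjusted p = 0.416 with an estimated correlation). Without KO library 1, 14 genes of that list rose, and without WT library 1, 1 did. Among 29 genes of the G2 and M phase list, Mki67 rose 1.25-fold, the 1 call over all genes, and 12 rose adjusted over the list alone; all 29 had a log2 fold change above 0 (median 0.24, camera adjusted p = 9.34e-08; adjusted p = 0.416 with an estimated correlation). Mki67 lost its call without KO library 2, KO library 3 or either WT library, while 6 genes of the list rose without KO library 1. The S phase list held 0 calls among 30 genes over all genes or adjusted over the list alone, and its median of 0.10 passed camera (adjusted p = 6.15e-04; adjusted p = 0.556 with an estimated correlation) except without WT library 2 (adjusted p = 0.334). In the NF-kB list of 23 genes the cytokine signalling inhibitor Socs3 fell 4.13-fold (7.93 ± 1.08 against 32.7 ± 6.76 CPM) and the interleukin-1 receptor Il1r1 1.54-fold, and 3 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.859). Without KO library 1, 3 of these genes fell and 2 rose, and without KO library 3 or either WT library 1 fell.

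Genes of DNA methylation and repair changed singly. Of 30 genes of DNA methylation and demethylation, Uhrf2, a binder of modified cytosine, rose 1.57-fold (144 ± 7.17 against 91.9 ± 5.99 CPM). Over all genes 1 rose and 1 fell, and adjusted over the list alone 1 rose and 2 fell (median -0.05, camera adjusted p = 0.255). The methylcytosine dioxygenase Tet2 stood at 34.1 ± 8.44 against 52.0 ± 0.741 CPM, a log2 fold change of -0.61 ± 0.17 that did not pass over all genes (adjusted p = 0.11) but passed adjusted over the list alone (adjusted p = 0.0367). Tet1 (-0.34 ± 0.15), Tet3 (-0.16 ± 0.16) and the methyltransferases Dnmt3a (-0.03 ± 0.11) and Dnmt3b (-0.005 ± 0.092) did not pass either. Among 29 base excision and mismatch repair genes, the repair polymerase Polb rose 1.73-fold, the 1 call over all genes and adjusted over the list alone (camera adjusted p = 0.0528, but 0.0476 without KO library 2, 0.0441 with DESeq2 and 0.0438 with limma and sample weights). Of 24 p53 targets, Trp53inp1 fell 1.39-fold over all genes, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.859).

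Few metabolic genes changed, and no ribosomal protein gene passed. Of 19 glycolysis genes, Pdk1, the kinase that inhibits pyruvate dehydrogenase, fell 1.52-fold (152 ± 4.74 against 231 ± 1.63 CPM), the 1 call over all genes and adjusted over the list alone (camera adjusted p = 0.108, 0.0428 with DESeq2; 2 fell without KO library 1). Of 73 oxidative phosphorylation genes, Ndufa4 rose 1.35-fold over all genes and 0 passed adjusted over the list alone. That list passed camera with a median of 0.10 (adjusted p = 0.00443; adjusted p = 0.605 with an estimated correlation), lost without KO library 1 (adjusted p = 0.103), without WT library 2 (adjusted p = 0.11) and with an offset for transcript length (adjusted p = 0.0648). The 83 cytosolic ribosomal protein genes (median 0.04, camera adjusted p = 0.538) and 14 histone genes (median -0.30, camera adjusted p = 0.489) held 0 calls over all genes or adjusted over the list alone, although 1 ribosomal protein gene rose without KO library 1. In all, 11 lists passed camera, 0 with an estimated correlation and 0 by fry, whose lowest directional adjusted p was 0.103.

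**Figure D2:**
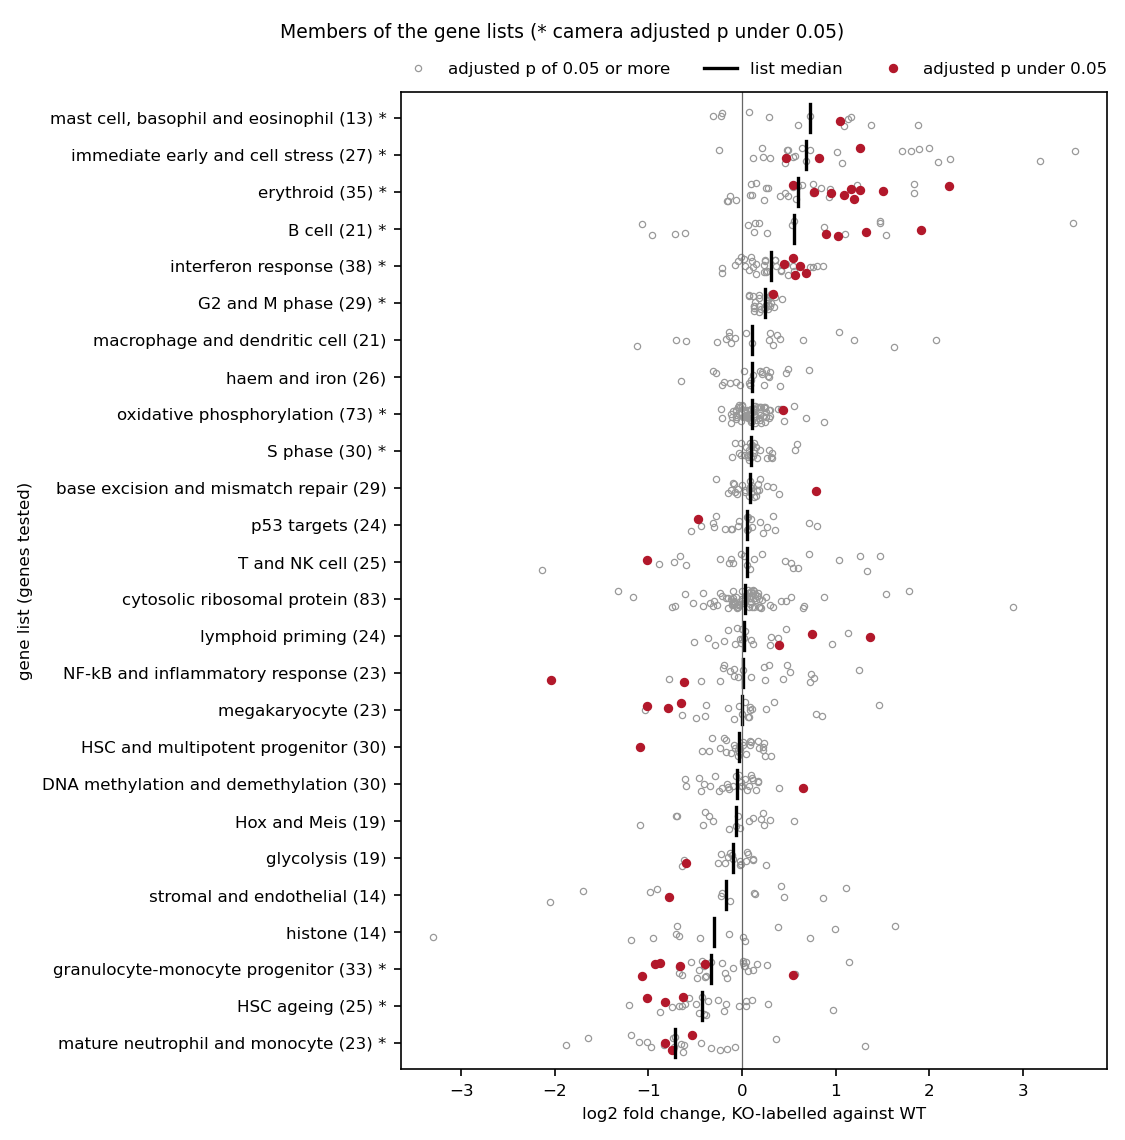
Log2 fold change, KO-labelled against WT, of members of the gene lists, with 1 row per list and the number of tested genes in brackets; red points passed an adjusted p of 0.05 over all genes, bars are list medians and asterisks mark lists past camera. Medians ran from -0.72 in the mature neutrophil and monocyte list to 0.72 in the mast cell, basophil and eosinophil list.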

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

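Summed transcripts, every transcript tested, protocadherin gamma genes counted once and the length and GC offsets were chosen after the results were seen. The counts of changed, higher and lower genes were 575, 264 and 311 with DESeq2, 567, 218 and 349 with limma and sample weights, 455, 200 and 255 with no count filter, and 449, 182 and 267 over every transcript. They were 77, 33 and 44 with a 2-fold minimum, 454, 192 and 262 at an adjusted p under 0.10, and 2007, 984 and 1023 at an unadjusted p under 0.05. With 1 library left out they ranged from 6 to 675 changed, 2 to 312 higher and 4 to 363 lower; leaving out a WT library left 1 WT sample, assumed to vary like the others. With the replicate number as a block (replicate block) 160 genes passed, 54 higher and 106 lower, and 142 of them were among the 287. Deviations from the group means correlated at 0.043 and 0.017 between same-numbered libraries. With only 2 WT libraries, their deviations mirror each other, so this check cannot decide whether the numbers pair the samples. Other scalings gave 284 and 285 genes, the length offset 352 and the GC offset 314. No call changed sign in any setting that tested 1 value per gene. Fewer samples left fewer calls when a WT library was dropped; the cause of the other gains and losses was not tested. Lists past camera numbered 9 to 14, except 7 without WT library 2 (range over left-out libraries 7 to 11), 0 with an estimated correlation and 0 by fry; the replicate block gave 12. Among values of named genes under the alternatives, 1420 kept their side of the threshold, 198 lost it and 11 gained it.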

Other observations

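The 8 lists in this part were chosen only after results were seen, as were the rule on abundant markers applied to the plasmacytoid list and the separate tests of macrophage and of dendritic cell genes. Because these same results led to the lists, their camera p-values, adjusted over the 8 lists alone, cannot count as independent support. Of 18 chaperone and stress genes of the endoplasmic reticulum, 5 rose and 0 fell over all genes (Hspa5, Herpud1, Xbp1, Creld2 and Sdf2l1), and 11 rose adjusted over the list alone (median 0.29, camera adjusted p = 1.24e-08; adjusted p = 0.152 with an estimated correlation). Hspa5, the main chaperone of that compartment, had a log2 fold change of 0.58 ± 0.08. Genes that respond to cytokines through STAT5 moved both ways, although Csf2rb and Csf2rb2 may share reads and so may not be separate calls. Of 12, Socs3 (-2.05 ± 0.19), Csf2rb (-1.07 ± 0.11), Pim2 (-1.01 ± 0.13) and Csf2rb2 (-1.23 ± 0.18) fell and the cyclin Ccnd2 rose (0.60 ± 0.08), with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00276; adjusted p = 0.152 with an estimated correlation). Of 10 MHC class I genes, 0 passed over all genes and 2 rose adjusted over the list alone, B2m and H2-K1 (camera adjusted p = 0.0804).

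Some heat shock genes rose, and the cold-inducible RNA-binding protein Cirbp fell (-1.16 ± 0.12). Of 19 heat shock factor targets, 6 rose and 0 fell, and 13 rose adjusted over the list alone (camera adjusted p = 1.56e-11; adjusted p = 0.152 with an estimated correlation); of 12 cold-inducible and splicing regulators, 4 fell and 1 rose, and 6 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.0126; adjusted p = 0.152 with an estimated correlation). Stress during dissociation and sorting may contribute: immediate early genes, heat shock genes left out, had a median of 0.638 (95% bootstrap bounds 0.476 to 1.072, 21 genes), although against the WT mean KO library 1 had 0.112, within the WT libraries' 0.114, and 0.458 for heat shock targets. A different time of day stays open, since 2 of 18 clock genes, Bhlhe40 and Rora, passed adjusted over the list alone, fewer than the 3 set beforehand (camera adjusted p = 0.729). Effects of the genotype on these genes were not separated from handling, because the labels give no sorting day.

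Cd74, H2-Aa, H2-Ab1 and H2-Eb1 rose, 4 of 11 MHC class II genes over all genes and adjusted over the list alone (camera adjusted p = 0.00133; adjusted p = 0.152 with an estimated correlation). The values do not decide on more macrophages: 16 of their genes had a median of -0.096 (-0.177 to 0.287), under 0.5. These genes were set apart only after their values were seen, which took rising dendritic cell genes out. The bounds also carry no spread between libraries. Dendritic cells stay open: 5 of their genes, Xcr1 (11.3 against 4.96 CPM), Siglech (4.19 against 1.36 CPM), Clec9a, Itgax and Cd209a, had a median of 1.19 (0.403 to 2.07), but were set apart after their values were seen. Pooled as fixed beforehand, the 21 genes had a median of 0.108 (-0.135 to 0.373), under the bound of 0.5 that would have counted against both, but these parts moved apart, so it decides nothing. Stronger interferon signalling may contribute, with a median of 0.309 (0.194 to 0.457) over 38 genes. Its camera call was lost at adjusted p = 0.416 with an estimated correlation. These values are those of the interferon list described in Results, so they add no separate support. B cells stay open at 0.398 (0.093 to 1.175) over 18 genes, although the sort removed lineage-positive cells. So do plasmacytoid dendritic cells: their 19 genes had a median of -0.053 (-0.137 to 0.009), under the bound of 0.3 written beforehand, which by itself would have counted against them, but 10 of the 19 exceeded 20 CPM in WT and could hide a small share, and the other 9 gave 0.128 (-0.121 to 1.4).

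Of the 10 splits of the 5 libraries into 3 and 2, 1 gave as many calls, the titled one with 287, and the highest other gave 6; the splits are too few for a share under 0.05. Transcript length went with the deviation of KO library 1 across 12617 genes (Spearman -0.265, against 0.036 to 0.111 in the others). For GC content the values were -0.133, 0.103 and 0.073 in KO libraries 1 to 3 and -0.183 and 0.21 in WT libraries 1 and 2; genes are not independent replicates. Tsix had 228 counts in KO library 1 and 1068 to 1806 elsewhere.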
